A study of Homo sapiens with 16 samples.

How the data were processed

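RNA was profiled in SAS cells, an established human line from a squamous cell carcinoma of the tongue, left untreated or exposed to 1 of 2 DNA G-quadruplex binders known here only by the code names cAQ-mBen and AQ-ac. Per the labels' protocols, cells were treated at 70% confluence, total RNA was isolated with a column kit and cDNA was made by the SMART method. Groups were taken from the sample titles: untreated cells, cAQ-mBen at 1 µM, cAQ-mBen at 5 µM and AQ-ac at 1 µM, each at an early time point and at 24 h, with 2 libraries in each of the 8 groups. The titles write the doses without the micro sign, and the unit comes from the treatment protocol. That protocol lists 1 and 5 µM for both compounds, and the titles hold AQ-ac at 1 µM only. For the earlier time the titles give 0 h where the protocol gives 6 or 24 h, so that group is called the early time point throughout. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

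The files hold whole-number read counts per gene made with HTSeq by the authors and deposited with 5 summary lines in each file. Per the submitters' processing notes, bcl2fastq, STAR and HTSeq were used with the GRCh38 build, and their versions, filters and the use of strand are not given in the sources used here. The 58721 gene identifiers all occur with their version and gene name in GENCODE release 29, which gave symbols, coordinates and gene types on GRCh38. The summary lines were left out of library sizes and tests. They put 43.1 to 44.2% of reads in no gene, though some may lie opposite one (strand use unknown). They put 2.39 to 2.50% in more than 1 gene and 5.35 to 6.52% at more than 1 position. With 2.74 to 5.82% not aligned, 42.7 to 44.9% were left in genes. Totals over genes ran from 11828558 to 17378653 per library (median 14057237), and 20742 to 23933 genes had at least 1 count.

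Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups and a minimum count of 10, which left 17049 genes. Libraries were scaled by TMM. A quasi-likelihood model with 1 mean per group was fitted to all 16 libraries, with 8 residual degrees of freedom, a median prior of 9.1 and a biological coefficient of variation of 13.8%. Each comparison was tested with the 2-sided quasi-likelihood F test, and p-values were adjusted by Benjamini-Hochberg over the 17049 genes, with a threshold of 0.05. Log2 changes are fitted values ± SE, CPM values are TMM-scaled means ± SD over the 2 libraries of a group, and 95% intervals use a t quantile of 2.11 at 17.1 degrees of freedom. A gene with no count in 1 group is given as a lower bound against a floor of 3 counts over that group. A gene with 1 to 3 counts is given as a ratio with its exact counting interval, and floors and counting intervals cover counting error only. Groups whose libraries did not overlap were also counted, which chance gives for 33.3% of genes at 2 against 2.

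Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with adjustment over the 26 lists of at least 5 tested genes within a comparison. Of 29 lists, those for fibroblast, leukocyte and endothelial markers had too few tested members. The lists were p53 target genes, homologous recombination and Fanconi repair, DNA replication, mitosis, replication-dependent histones, ATF4 and the integrated stress response, endoplasmic reticulum chaperones, interferon-stimulated genes, NF-kappaB targets and inflammatory cytokines, keratinocyte differentiation, basal keratinocyte genes, epithelial-mesenchymal transition, cholesterol biosynthesis, lysosome and autophagy, NRF2 and oxidative stress, aryl hydrocarbon receptor targets, hypoxia and glycolysis, genes with published promoter G-quadruplexes, telomere and telomerase, G-quadruplex helicases, ribosome biogenesis, cytosolic ribosomal proteins, mitochondrially encoded genes, immediate-early genes, heat shock, apoptosis regulators and the 3 lists of other cell types. A preset correlation of 0.01 gives far smaller p-values than an estimated one. Of 69 list calls over all comparisons, 6 held with an estimated correlation, so each is printed with both. The 6 were immediate-early genes in 4 comparisons, NF-kappaB targets over time in untreated cells and mitosis between doses at 24 h.

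The groups, comparisons, tests, gene lists and rule for named genes were fixed before the data were examined. For 5 µM cAQ-mBen against untreated cells the rule took the 10 largest rises and 10 largest falls at each time among genes past the test, with a mean of at least 5 CPM in the higher group, a gene symbol and no overlap of libraries. It took 5 and 5 for the other comparisons of 2 groups and 3 and 3 for the differences of an effect between times. Each list past its test added the 3 members with the smallest adjusted p in its direction, and CDKN1A, MYC, KIT, TERT, CYP1A1 and HMGCS1 were always included. KIT was not among the tested genes. The text gives a subset of these genes.

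Alternatives planned before the data were examined were RLE scaling, no filter on low counts (33776 genes), a filter of 1 CPM in 2 libraries (15960 genes), DESeq2 1.42.0, the replicate number as a block, a fit to the compared libraries alone, leaving out each library in turn, and, for lists, an estimated correlation and fry. Thinning every library to the lowest gene total, removing a GC trend per library, leaving out the genes of the mitochondrial genome, and leaving out each library for the list tests and the correlations were added after the data had been seen. Comparisons of treatments with the same untreated libraries were set beside 100 simulations of unchanged groups. In counts simulated for 5 µM cAQ-mBen at 24 h, with 200 of 17049 genes changed, 32% of changed genes were recovered at 1.5-fold, 48% at 2-fold, 78% at 3-fold and 86% at 4-fold. There were 4 false calls among 126, and 0 calls in an unchanged comparison. Tables were joined with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.

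Whether reads of overlapping genes on opposite strands were kept apart was checked after the summary lines had been seen. Among 248 genes with over 90% of their exonic bases under an opposite-strand gene of over 5000 counts, read density was a median 1.52 times that of the partner (quartiles 0.418 and 3.14). Their values correlated with the partner's over the 16 libraries at a median of 0.791, against 0.0436 with the partner of another gene. Counts of such pairs cannot be told apart here, and shares on the opposite strand over 20% are given beside the gene, as are those of C6orf52 and ADAP2. Of other genes named, FDPS shares 18.6%, HMGCS1 15%, IDI1 14.8%, PLK1 11.6%, RPS6 10.4%, CALR 9.95%, ELF3 9.23% and SLC7A11 8.97%. Counts of genes with near-identical copies, such as HSPA1A and HSPA1B, NPIPB2 and the pseudogene KRT18P55, are uncertain too, since reads at more than 1 position were left out of genes.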

Results

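The libraries profiled gene expression in SAS tongue carcinoma cells without treatment and with the DNA G-quadruplex binders cAQ-mBen and AQ-ac, and the design asks which genes each compound, dose and time altered. Each of the 8 groups had 2 libraries. Replicates correlated at 0.977 to 0.981 over genes in log2 CPM, and differed by more than sampling noise in every group (chi-square per degree of freedom 6.45 to 12.7). The first principal component, with 29.3% of the variance, placed untreated and AQ-ac libraries at -40.79 to -28.26, 1 µM cAQ-mBen at 6.29 to 29.48 and 5 µM cAQ-mBen at 30.4 to 80.19. The second, with 17.2%, was positive in all early libraries and negative in all 24 h libraries. With AQ-ac 4.32% ± 0.11 (SD, n = 2) of reads were not aligned at the early time point and 2.92% ± 0.11 at 24 h, against 4.26% ± 0.19 and 2.9% ± 0.23 in untreated cells.

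**Figure D1:**
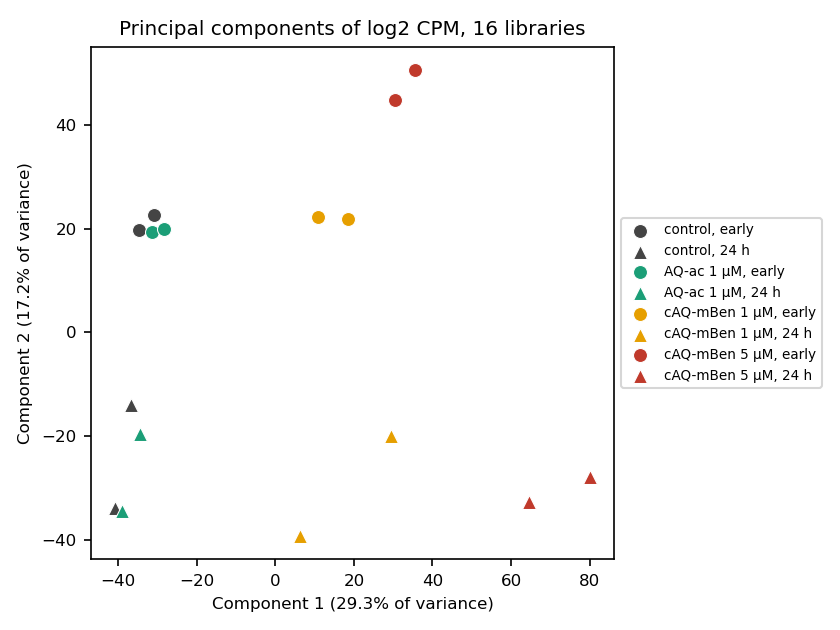
Principal components of log2 CPM, with 1 point per library, colour for treatment and marker for time. The first component separates cAQ-mBen libraries, above 6, from untreated and AQ-ac libraries, below -28, and the second separates the times.

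At the early time point, 5 µM cAQ-mBen lowered single genes such as HSPA8 and TERT and raised others such as ICAM1, GADD45A and MYC. HSPA8, an abundant cytosolic chaperone of the HSP70 family, went from 3390 ± 134 CPM in untreated cells to 358 ± 161 CPM (9.49-fold lower, log2 change -3.25 ± 0.23, adjusted p = 8.11e-08). ICAM1, a cell adhesion molecule, rose 5.99-fold from 99.9 ± 16.8 to 599 ± 177 CPM, GADD45A, a stress-inducible growth arrest gene, rose 5-fold from 101 ± 4.53 to 504 ± 42 CPM, and PPP1R15A, which encodes a regulatory subunit of an eIF2-alpha phosphatase, rose 5.61-fold from 78.3 ± 3.55 to 440 ± 73.5 CPM. The proto-oncogene MYC rose 2.45-fold from 355 ± 51 to 870 ± 16.5 CPM (log2 change 1.3 ± 0.13, adjusted p = 2.61e-06), and TERT, the catalytic subunit of telomerase, fell 4.31-fold from 14.9 ± 2.19 to 3.47 ± 0.711 CPM (log2 change -2.11 ± 0.33, adjusted p = 0.000217). The cyclin-dependent kinase inhibitor CDKN1A rose 2.51-fold (log2 change 1.33 ± 0.19, adjusted p = 0.000105).

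The largest rises were in genes that were near silent in untreated cells. KRT18P55, a transcribed keratin pseudogene at chromosome 17, 28275986 to 28317783, had 170 counts against 0 and was at least 62.7-fold higher (adjusted p = 0.00012). C6orf52 (ENSG00000137434.11, chromosome 6, 10671418 to 10694797) rose 18.4-fold to 14.6 ± 0.547 CPM (adjusted p = 4.18e-07), and 10.7% of its exonic bases lie under PAK1IP1 on the opposite strand. ADAP2 rose 21-fold (log2 change 4.39 ± 0.37, adjusted p = 4.4e-07), and by 5.35 on that scale without replicate 2 of the early untreated cells. On the opposite strand AC138207.1, itself higher (log2 change 7.87, adjusted p = 0.000174), and TEFM (-0.33) cover 8.67% and 8.03% of its exonic bases. The stress-responsive transcription factor ATF3 rose 18.5-fold to 25.1 ± 12.7 CPM (log2 change 4.21 ± 0.56, adjusted p = 4.66e-05). The ATF3 log2 change was 4.84 without replicate 1 of the early untreated cells and 3.58 without replicate 2 of 5 µM cAQ-mBen. Among the falls were the bradykinin receptor BDKRB2 (11.3-fold, adjusted p = 3.23e-06) and SLFN11, a factor that blocks stressed replication forks (8.55-fold, from 50.4 ± 0.959 to 5.9 ± 0.373 CPM, adjusted p = 1.67e-06). The test called 3848 of 17049 genes, 1835 higher and 2013 lower, of which 600 and 686 changed over 2-fold, and libraries of the groups did not overlap for 10570 genes. The count was 2496 without replicate 1 and 2217 without replicate 2 of the early untreated cells, and 1874 without replicate 2 of 5 µM cAQ-mBen.

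**Figure D2:**
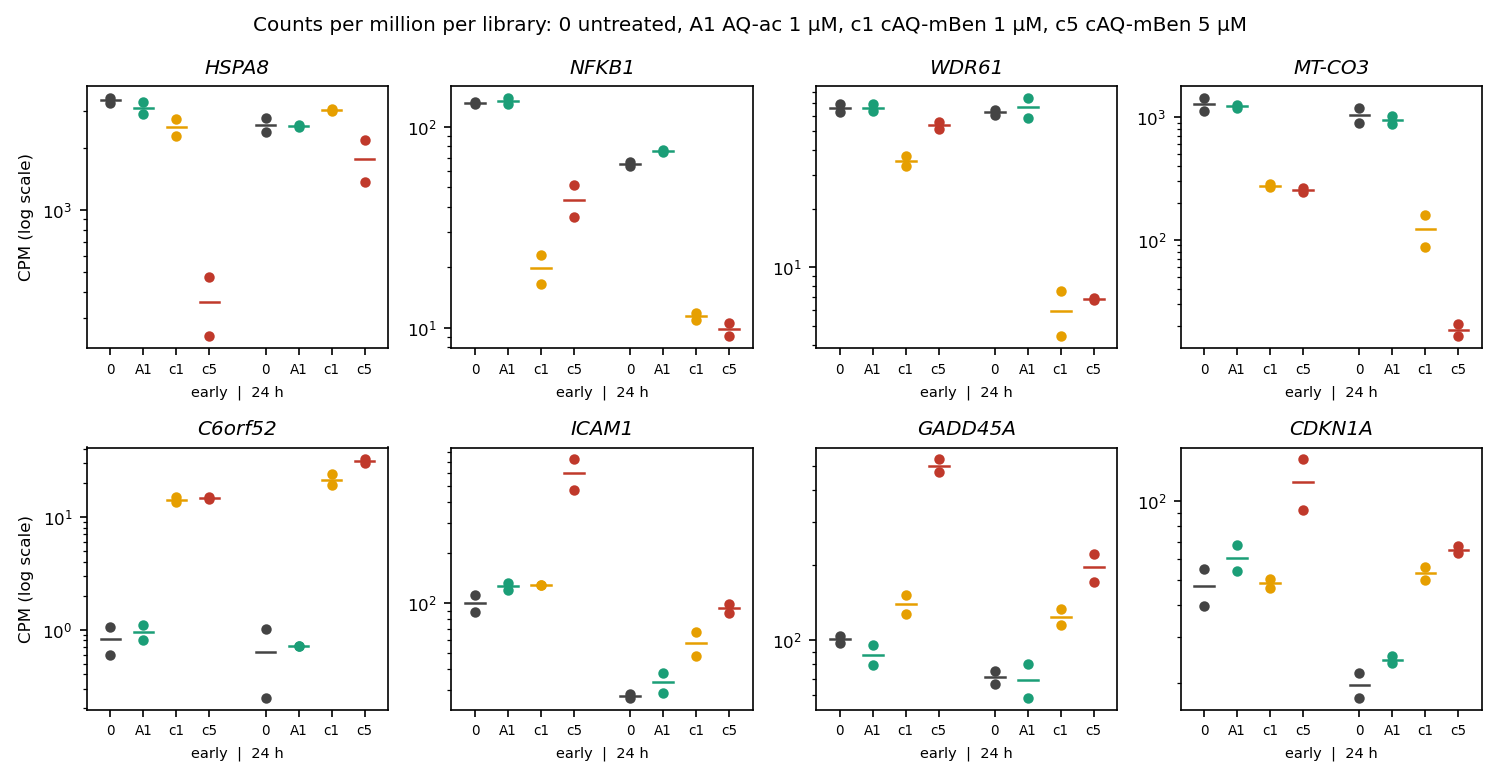
CPM of 8 genes in each library on a log axis, with points for the 2 libraries of a group and lines for their mean. HSPA8 stands at 358 CPM after 5 µM cAQ-mBen at the early time point against 3390 CPM in untreated cells, and MT-CO3 at 18.5 CPM against 1040 CPM at 24 h.

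Of 26 gene lists, 9 passed the camera test for 5 µM cAQ-mBen at the early time point, 5 upward and 4 downward. Immediate-early genes were the strongest upward, with 12 of 19 members higher and 0 lower (16 and 0 adjusted over the list alone). The median log2 change over the list was 1.35, with adjusted p = 6.35e-08 (adjusted p = 0.00588 with an estimated correlation). Among them the transcription factor EGR1 rose 4.93-fold from 65.7 ± 0.34 CPM (adjusted p = 9.59e-08) and KLF6 rose 2.77-fold (adjusted p = 6.67e-06). NF-kappaB targets had 10 of 16 higher and 1 lower (11 and 1 adjusted over the list alone), including the chemokine CXCL8, which rose 7.82-fold from 9.61 ± 1.57 to 75.5 ± 19.8 CPM, and the pathway inhibitor NFKBIA, up 1.85-fold. The median was 1.17, with adjusted p = 0.000201 (adjusted p = 0.271 with an estimated correlation). ICAM1 shares 22% of its exonic bases with AC011511.5 on the opposite strand. Integrated stress response genes had 9 of 18 higher and 0 lower (10 and 1 adjusted over the list alone). The median was 0.72, with adjusted p = 0.000108 (adjusted p = 0.117 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, rose 2.43-fold, with 27.2% of its exonic bases under MARS. Of 24 p53 target genes 10 rose and 1 fell (10 and 1 adjusted over the list alone), and the growth factor family member GDF15 rose 4.01-fold (adjusted p = 2.93e-05). The median was 0.41, with adjusted p = 0.0032 (adjusted p = 0.259 with an estimated correlation). Cytosolic ribosomal protein genes had 8 of 28 higher and 0 lower by small amounts (11 and 0 adjusted over the list alone), with RPS6 up 1.25-fold from 1420 ± 38.8 to 1790 ± 54.4 CPM. The median was 0.16, with adjusted p = 0.000987 (adjusted p = 0.455 with an estimated correlation).

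The 4 downward lists at this time were led by mitochondrially encoded genes, with 9 of 13 lower and 1 higher (11 and 2 adjusted over the list alone). The median was -1.87, with adjusted p = 6.44e-07 (adjusted p = 0.273 with an estimated correlation). DNA replication genes had 11 of 22 lower and 0 higher (11 and 0 adjusted over the list alone), and PCNA, the sliding clamp of DNA polymerases, fell 2.72-fold from 207 ± 14.4 to 76 ± 8.9 CPM (adjusted p = 6.28e-07). The median was -0.38, with adjusted p = 0.000108 (adjusted p = 0.273 with an estimated correlation). Heat shock genes had 8 of 14 lower and 0 higher (8 and 0 adjusted over the list alone). The median was -0.41, with adjusted p = 0.000179 (adjusted p = 0.273 with an estimated correlation). The inducible HSP70 genes HSPA1A and HSPA1B, whose reads may be divided between near-identical copies, were 8.13-fold and 9.03-fold lower. G-quadruplex helicases had 7 of 14 lower and 0 higher (8 and 0 adjusted over the list alone), with PIF1 5.11-fold lower (adjusted p = 1.13e-05) and the TFIIH helicase ERCC3 1.97-fold lower (adjusted p = 2.78e-05). The median was -0.5, with adjusted p = 0.000754 (adjusted p = 0.117 with an estimated correlation). CYP1A1 (log2 change 1.9 ± 1.07, adjusted p = 0.225) and HMGCS1 (0.17 ± 0.26, adjusted p = 0.691) did not pass the test. The share of reads not aligned was 5.34% ± 0.58 in these treated libraries against 4.26% ± 0.19 in untreated ones.

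**Figure D3:**
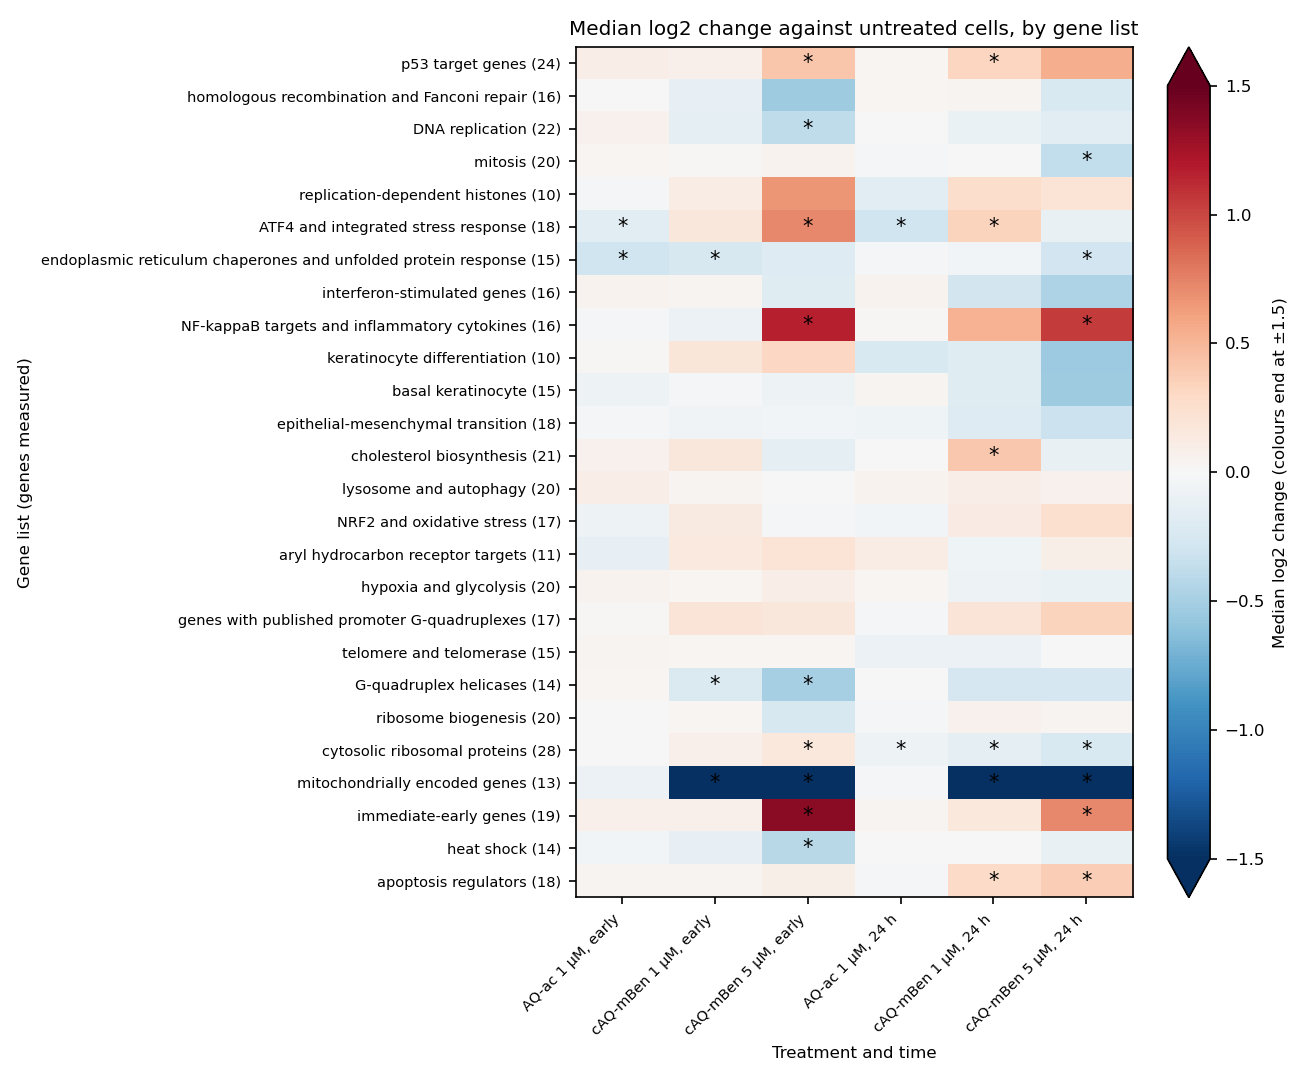
Median log2 change of 26 gene lists in the 6 comparisons of a treatment with untreated cells, with colours that end at -1.5 and 1.5 and asterisks for lists past the camera test at the preset correlation. Mitochondrially encoded genes pass in all 4 cAQ-mBen comparisons and reach a median of -3.57 for 5 µM at 24 h.

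At 24 h, 5 µM cAQ-mBen left some mitochondrial mRNAs at a small part of their untreated level, lowered HSPA5 and raised CDKN1A and ICAM1. MT-CO3, a subunit of cytochrome c oxidase, went from 1040 ± 209 to 18.5 ± 3.12 CPM (55.8-fold lower, log2 change -5.8 ± 0.24, adjusted p = 7.24e-11), and MT-ND4, a subunit of respiratory complex I, from 1290 ± 237 to 28.7 ± 8.71 CPM (44.7-fold lower, adjusted p = 1.86e-10). HSPA5, the main chaperone of the endoplasmic reticulum, fell 2.26-fold from 1020 ± 13.6 to 450 ± 16.5 CPM (adjusted p = 5.65e-08). CDKN1A rose 3.31-fold from 19.6 ± 2.98 to 65.1 ± 2.86 CPM (adjusted p = 4.46e-06), and ICAM1 rose 3.34-fold (adjusted p = 2.47e-06).

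Genes near silent in untreated cells again led the rises. RRH, a gene of the opsin family at chromosome 4, 109827994 to 109844604, had 216 counts against 0 (at least 68.4-fold higher, adjusted p = 6.24e-06), and the orphan receptor gene GPR19 had 199 against 0 (at least 63-fold higher, adjusted p = 4.36e-05). NPIPB2, a member of a family of near-identical copies, rose 95.7-fold to 16.8 ± 3.19 CPM (adjusted p = 5.16e-08) and ADAP2 rose 33.1-fold to 21.2 ± 0.529 CPM. C6orf52 rose 50.7-fold to 31.1 ± 1.41 CPM (log2 change 5.66 ± 0.35, adjusted p = 5.22e-09), with values of 4.93 and 6.92 without replicate 1 or replicate 2 of the 24 h untreated cells. The kinase gene CDK18 fell 20.4-fold from 11.8 ± 2.83 to 0.573 ± 0.0631 CPM (adjusted p = 1.6e-06), and WDR61, a subunit of the PAF1 complex, fell (log2 change -3.19, adjusted p = 2.96e-09), as did NFKB1, which encodes a subunit of NF-kappaB (log2 change -2.73, adjusted p = 7.15e-09). MYC (log2 change -0.2 ± 0.13, adjusted p = 0.243), TERT (0.05 ± 0.3, adjusted p = 0.906), CYP1A1 (0.31, adjusted p = 0.851) and HMGCS1 (0.3, adjusted p = 0.371) did not pass the test, though without replicate 1 of 5 µM cAQ-mBen the MYC value was -0.39 (adjusted p = 0.0386). The test called 6267 genes, 2975 higher and 3292 lower, of which 1080 and 1430 changed over 2-fold, and libraries of the groups did not overlap for 11535 genes.

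Among the lists at 24 h, mitochondrially encoded genes had 12 of 13 lower and 0 higher (12 and 0 adjusted over the list alone). The median was -3.57, with adjusted p = 5.4e-13 (adjusted p = 0.154 with an estimated correlation). Mitosis genes had 13 of 20 lower and 2 higher (13 and 2 adjusted over the list alone), and topoisomerase TOP2A fell 2.42-fold from 419 ± 47.2 to 173 ± 64.1 CPM and the mitotic kinase AURKB 1.52-fold. The median was -0.36, with adjusted p = 0.00293 (adjusted p = 0.141 with an estimated correlation). Cytosolic ribosomal protein genes had 17 of 28 lower and 1 higher (19 and 1 adjusted over the list alone), with RPL3 1.72-fold lower. The median was -0.23, with adjusted p = 0.00202 (adjusted p = 0.494 with an estimated correlation). Endoplasmic reticulum chaperones had 9 of 15 lower and 1 higher (9 and 1 adjusted over the list alone), with the disulfide isomerase PDIA4 2.07-fold lower. The median was -0.28, with adjusted p = 0.0261 (adjusted p = 0.431 with an estimated correlation). Immediate-early genes had 8 of 19 higher and 0 lower (10 and 0 adjusted over the list alone), with the phosphatase gene DUSP1 up 2.26-fold. The median was 0.72, with adjusted p = 0.00835 (adjusted p = 0.141 with an estimated correlation). NF-kappaB targets had 7 of 16 higher and 1 lower (10 and 1 adjusted over the list alone), including the inhibitor TNFAIP3, up 5.56-fold, and the cytokine LIF, up 3.95-fold. The median was 1.05, with adjusted p = 0.0179 (adjusted p = 0.431 with an estimated correlation). Apoptosis regulators had 6 of 18 higher and 1 lower (6 and 1 adjusted over the list alone), with the BH3-only gene PMAIP1 up 3.23-fold. The median was 0.37, with adjusted p = 0.0373 (adjusted p = 0.154 with an estimated correlation). The adjusted p of NF-kappaB targets was 0.0542 without replicate 1 and that of chaperones 0.0819 without replicate 2 of the 24 h untreated cells, and that of apoptosis regulators 0.09 without the latter and 0.0524 without replicate 2 of 5 µM cAQ-mBen. In these treated libraries 5.09% ± 1.03 of reads were not aligned, against 2.9% ± 0.23 in untreated ones.

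Several lists passed in no comparison. At 24 h with 5 µM cAQ-mBen, genes with published promoter G-quadruplexes had 7 of 17 members higher and 1 lower (adjusted p = 0.192), basal keratinocyte genes 1 and 8 of 15 (adjusted p = 0.291), interferon-stimulated genes 0 and 6 of 16 (adjusted p = 0.187), and telomere and telomerase genes 4 and 3 of 15 (adjusted p = 0.979). Histones had 1 higher and 3 lower of 10 (adjusted p = 1), keratinocyte differentiation genes 2 and 0 of 10 (adjusted p = 0.979), lysosome and autophagy genes 8 and 7 of 20 (adjusted p = 0.847), NRF2 and oxidative stress genes 5 and 4 of 17 (adjusted p = 0.847), aryl hydrocarbon receptor targets 0 and 1 of 11 (adjusted p = 1), and hypoxia and glycolysis genes 4 and 6 of 20 (adjusted p = 0.898). Among markers of other cell types, 3 of 11 for fibroblasts, 1 of 11 for leukocytes and 3 of 9 for endothelium were measured, with 0 higher and 1, 0 and 0 lower.

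Along the mitochondrial genome, cAQ-mBen lowered the mRNAs of the middle and distal part of the heavy-strand transcript more than those near its start. For 5 µM the Spearman rho of log2 change with gene start was -0.909 early and -0.79 at 24 h. It was taken over 12 mRNAs that are not independent replicates (permutation p = 0.00011 and 0.0032, adjusted over 6 comparisons 0.00022 and 0.0048). The test was chosen only after its result was seen, so these p-values give no independent support. At the early time point with 5 µM, MT-CYB, a subunit of complex III at positions 14747 to 15887, went from 922 ± 199 to 127 ± 11.5 CPM (7.27-fold lower, adjusted p = 1.72e-08), MT-ND5 was 5.57-fold lower and MT-CO3, at 9207 to 9990, had a log2 change of -2.31. MT-ND1, close to the start, had a log2 change of 0.67 (adjusted p = 0.0208), and the small ribosomal RNA MT-RNR1, named after its values were seen, had 1.18 (adjusted p = 0.0011). At 24 h with 5 µM the log2 changes were -0.26 for MT-ND1 (adjusted p = 0.334), -1.07 for MT-CO1, -5.8 for MT-CO3, -4.53 for MT-ND3, -5.48 for MT-ND4, -4.6 for MT-ND5 and -3.94 for MT-CYB, and 1.81 for MT-RNR1 (adjusted p = 1.02e-05). MT-ND6, on the light strand, had -1.93 early and -2.98 at 24 h, but its reads may be of either strand. With AQ-ac 0 of these passed the gene test. Values ran from -0.21 for MT-CYB to 0.39 for MT-ND1 early and from -0.17 for MT-ND3 to 0.28 for MT-ND1 at 24 h. AQ-ac had a rho of the same sign, -0.75 early (permutation p = 0.0062, adjusted 0.0074) and -0.502 at 24 h (permutation p = 0.098). No value was simulated for the sharing of untreated libraries. All mitochondrial genes together took 1.37% ± 0.22 of gene counts after 5 µM cAQ-mBen at 24 h, 1.79% ± 0.32 in untreated cells and 1.82% ± 0.25 with AQ-ac.

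**Figure D4:**
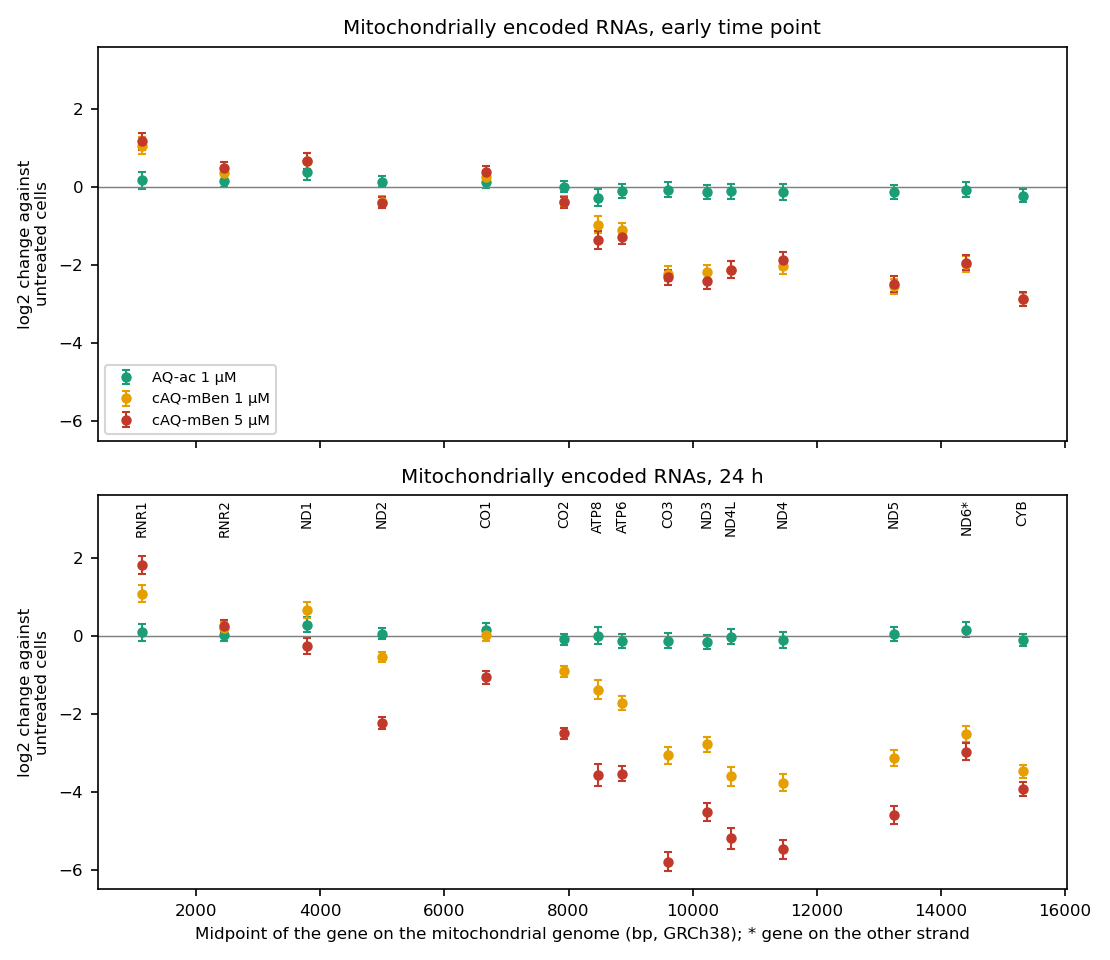
Log2 change of each mitochondrial gene (vertical axis, bars ± SE) against its midpoint on the mitochondrial genome (horizontal axis) for the 3 treatments, with the early time point and 24 h in separate panels and an asterisk for MT-ND6 on the other strand. For 5 µM cAQ-mBen at 24 h the values drawn run from 1.81 at MT-RNR1 to -5.8 at MT-CO3.

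At 1 µM, cAQ-mBen at the early time point lowered single genes such as NFKB1 and MT-CYB, and raised KRT18P55, C6orf52 and ADAP2, which were also among the large rises at 5 µM. NFKB1 (chromosome 4, 102501329 to 102617302) fell 6.67-fold from 131 ± 1.37 to 19.7 ± 4.56 CPM (log2 change -2.74 ± 0.17, adjusted p = 5.33e-08). MT-CYB fell 7.33-fold to 126 ± 15.7 CPM and MT-ND5 5.82-fold. KRT18P55 had 238 counts against 0 (at least 77.2-fold higher, adjusted p = 0.00029) and C6orf52 rose 17.8-fold (adjusted p = 1.75e-06). ADAP2 rose 20.2-fold (log2 change 4.34 ± 0.37, adjusted p = 1.92e-06), and by 5.29 on that scale without replicate 2 of the early untreated cells.

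Of the lists, mitochondrially encoded genes had 9 of 13 lower and 0 higher at this dose and time (11 and 1 adjusted over the list alone). The median was -1.96, with adjusted p = 2.83e-12 (adjusted p = 0.217 with an estimated correlation). Endoplasmic reticulum chaperones had 4 of 15 lower and 0 higher (7 and 0 adjusted over the list alone), with HSPA5 1.78-fold lower, from 1570 ± 66.8 to 881 ± 130 CPM, and MANF, a stress-induced secreted factor, 1.61-fold lower (adjusted p = 0.000641). The median was -0.24, with adjusted p = 4.04e-05 (adjusted p = 0.217 with an estimated correlation). G-quadruplex helicases had 1 of 14 lower and 0 higher (4 and 1 adjusted over the list alone), the 1 being DHX36, an RNA and DNA G-quadruplex helicase that fell 1.75-fold (adjusted p = 0.000943). The median was -0.21, with adjusted p = 0.0221 (adjusted p = 0.217 with an estimated correlation). The helicase call was lost without replicate 1 of 1 µM cAQ-mBen (adjusted p = 0.058) and without replicate 2 of the early untreated cells (adjusted p = 0.0844). MYC (log2 change 0.42 ± 0.13, adjusted p = 0.0731), CDKN1A (0.03, adjusted p = 0.971), TERT (-0.31, adjusted p = 0.676), CYP1A1 (0.25, adjusted p = 0.952) and HMGCS1 (0.44, adjusted p = 0.422) did not pass the test, although MYC did with no filter on low counts (adjusted p = 0.000274), with DESeq2 (0.0309), with the replicate block (0.00301) and in the fit to the compared libraries alone (0.0308). The test called 673 genes, 276 higher and 397 lower, and libraries did not overlap for 8011. In these libraries 4.7% ± 0.08 of reads were not aligned, against 4.26% ± 0.19 in untreated ones. The count was 278 without replicate 1 and 267 without replicate 2 of the early untreated cells, and 348 and 236 without replicate 1 or 2 of 1 µM cAQ-mBen.

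At 24 h, 1 µM cAQ-mBen lowered MT-ND4 and MT-CYB and raised CDKN1A. MT-ND4 went from 1290 ± 237 to 94.3 ± 32 CPM (13.7-fold lower, adjusted p = 1.88e-08) and MT-CYB from 757 ± 190 to 67.9 ± 7.56 CPM (11.1-fold lower, adjusted p = 2.51e-09). WDR61 (chromosome 15, 78277835 to 78299794) fell 10.5-fold from 62.7 ± 2.63 to 5.97 ± 2.21 CPM (log2 change -3.39 ± 0.19, adjusted p = 1.24e-08). CDKN1A rose 2.68-fold to 52.8 ± 4.49 CPM (adjusted p = 0.000221), NPIPB2 rose 53.8-fold (adjusted p = 1.47e-06) and ADAP2 19.6-fold (adjusted p = 2.19e-07). C6orf52 rose 34.7-fold (log2 change 5.12 ± 0.35), and that value was 4.39 without replicate 1 and 6.38 without replicate 2 of the 24 h untreated cells.

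Mitochondrially encoded genes at this dose and time had 11 of 13 lower and 1 higher (11 and 1 adjusted over the list alone). The median was -2.53, with adjusted p = 7.08e-14 (adjusted p = 0.234 with an estimated correlation). Of p53 target genes 7 rose and 1 fell (9 and 2 adjusted over the list alone), including GADD45A, up 1.75-fold (adjusted p = 0.0026), and GDF15, up 2.26-fold (adjusted p = 0.00447, and 0.0558 without replicate 2 of the 24 h untreated cells). The median was 0.32, with adjusted p = 0.0183 (adjusted p = 0.397 with an estimated correlation). Integrated stress response genes had 3 higher and 0 lower (6 and 1 adjusted over the list alone), with PPP1R15A up 2.61-fold and the pseudokinase gene TRIB3 up 1.59-fold. The median was 0.34, with adjusted p = 0.0236 (adjusted p = 0.397 with an estimated correlation). Cholesterol biosynthesis had 4 of 21 higher and 0 lower (7 and 0 adjusted over the list alone). The median was 0.4, with adjusted p = 0.0116 (adjusted p = 0.621 with an estimated correlation). Ribosomal protein genes had 3 lower and 0 higher (7 and 0 adjusted over the list alone), with RPL3 1.43-fold lower. The median was -0.13, with adjusted p = 0.00902 (adjusted p = 0.621 with an estimated correlation). Apoptosis regulators had 3 higher and 0 lower (5 and 0 adjusted over the list alone). The median was 0.28, with adjusted p = 0.0116 (adjusted p = 0.234 with an estimated correlation). Their PMAIP1 was 2.52-fold higher (adjusted p = 0.00329, but 0.0649 without replicate 1 of the 24 h untreated cells and 0.0978 without replicate 2 of 1 µM cAQ-mBen).

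Several list calls were lost without 1 library. Without replicate 2 of the 24 h untreated cells the adjusted p was 0.139 for p53 targets, 0.113 for integrated stress response genes, 0.0635 for ribosomal protein genes and 0.0635 for apoptosis regulators, and without replicate 1 it was 0.0921 for cholesterol biosynthesis. Without replicate 1 of 1 µM cAQ-mBen it was 0.0671 for p53 targets and 0.103 for integrated stress response genes, without replicate 2 it was 0.0734 for ribosomal protein genes, and fry gave 0.157 for cholesterol biosynthesis. MYC (log2 change -0.18, adjusted p = 0.414), TERT (-0.13, adjusted p = 0.843), CYP1A1 (0.79, adjusted p = 0.706) and HMGCS1 (0.4, adjusted p = 0.347) did not pass the test. In these libraries 3.32% ± 0.6 of reads were not aligned, against 2.9% ± 0.23 in untreated ones. The test called 1853 genes, 900 higher and 953 lower, and libraries did not overlap for 8963. The count was 733 without replicate 1 and 1221 without replicate 2 of the 24 h untreated cells, 485 without replicate 2 of 1 µM cAQ-mBen and 689 in a fit to the compared libraries alone.

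AQ-ac at 1 µM had 0 genes past the edgeR test at either time. At the early time point 834 genes had an unadjusted p under 0.05, the smallest adjusted p was 0.607, libraries did not overlap for 5965 genes, and DESeq2 called 1 gene. No filter on low counts gave 14 calls and the replicate block 2. At 24 h 568 genes had an unadjusted p under 0.05, the smallest adjusted p was 1, libraries did not overlap for 5440 genes, DESeq2 called 0 and no filter gave 6. Among 9253 genes with a mean of at least 10 CPM, the 95% interval of the log2 change lay within 2-fold of untreated cells for 98.1% at the early time point and 98.5% at 24 h, against 93.3% and 88.8% for 1 µM cAQ-mBen and 81% and 72.1% for 5 µM. HSPA5 had a log2 change of -0.43 ± 0.09 at the early time point (interval -0.62 to -0.25, adjusted p = 0.823, but 4.26e-05 with no filter and 0.0235 with the replicate block). CDKN1A had 0.36 (interval -0.05 to 0.76) at the early time point and 0.32 (-0.11 to 0.75) at 24 h, MYC had -0.16 (-0.42 to 0.11) and -0.15 (-0.41 to 0.12), TERT had -0.64 (-1.27 to -0.01) and -0.4 (-1.04 to 0.25), and HMGCS1 had 0.07 (-0.47 to 0.60) and 0.10 (-0.43 to 0.64). CYP1A1, the classical target of the aryl hydrocarbon receptor, had a log2 change of -0.29 at the early time point and 1 count against 18 at 24 h (ratio 0.057, counting interval 0.00137 to 0.361).

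As sets, endoplasmic reticulum chaperones were lower with AQ-ac at the early time point (0 of 15 past the gene test, 0 higher and 5 lower adjusted over the list alone). The median was -0.3, with adjusted p = 3.94e-06 (adjusted p = 0.369 with an estimated correlation). Integrated stress response genes were lower at both times, with 0 of 18 past the gene test at each. At the early time point 0 passed adjusted over the list alone (median -0.17, adjusted p = 0.0337, and adjusted p = 0.76 with an estimated correlation), and at 24 h 0 were higher and 1 lower (median -0.3, adjusted p = 0.000939, and adjusted p = 0.46 with an estimated correlation). Ribosomal protein genes were lower at 24 h, with 0 past the gene test and 0 adjusted over the list alone (median -0.08, adjusted p = 0.000939, and adjusted p = 0.978 with an estimated correlation). With fry all 4 calls were lost, with adjusted p of 0.0746 for chaperones, 0.593 and 0.583 for integrated stress response genes and 0.917 for ribosomal protein genes. Without 1 library the early stress response call was also lost, with 0.232 and 0.118 without replicate 1 or 2 of the untreated cells and 0.479 without replicate 1 of AQ-ac. At 24 h that list had 0.0838 without replicate 1 of the untreated cells and 0.355 without replicate 2 of AQ-ac, and ribosomal protein genes had 0.0747 without replicate 2 of the untreated cells and 0.182 without replicate 2 of AQ-ac.

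Between 5 and 1 µM cAQ-mBen at the early time point, single genes differed in both directions. HSPA8 was 7.05-fold lower, at 358 ± 161 against 2520 ± 328 CPM (log2 difference -2.82 ± 0.23, adjusted p = 1.39e-06), and BDKRB2 11.5-fold lower (adjusted p = 8.94e-06). CXCL8 was 10.4-fold higher (adjusted p = 1.87e-05), ICAM1 4.66-fold higher (adjusted p = 1.39e-06), GADD45A 3.61-fold higher (adjusted p = 1.39e-06) and EGR1 3.49-fold higher (adjusted p = 3.83e-06). CDKN1A was 2.46-fold higher (log2 difference 1.3 ± 0.19, adjusted p = 0.00039) and MYC 1.83-fold higher (0.87 ± 0.13, adjusted p = 0.000363), while CYP1A1 (1.65, adjusted p = 0.384) and HMGCS1 (-0.27, adjusted p = 0.587) did not pass the test. TERT was 3.48-fold lower (log2 difference -1.8 ± 0.33, adjusted p = 0.00216), a call lost without replicate 2 of 5 µM cAQ-mBen (-1.58, adjusted p = 0.0648). Of 1615 genes called, 700 were higher and 915 lower, libraries did not overlap for 9061, and the count was 780 and 793 without replicate 1 or 2 of 1 µM and 415 without replicate 2 of 5 µM.

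Of the 10 lists past the test, of which 1 held with an estimated correlation, given as members higher and lower at 5 µM, immediate-early genes had 12 and 0 (15 and 0 adjusted over the list alone). The median was 1.26, with adjusted p = 3.9e-11 (adjusted p = 0.00179 with an estimated correlation). NF-kappaB targets had 9 and 0 (12 and 0 adjusted over the list alone). The median was 1.1, with adjusted p = 5.12e-07 (adjusted p = 0.132 with an estimated correlation). Integrated stress response genes had 7 and 1 (8 and 1 adjusted over the list alone). The median was 0.38, with adjusted p = 0.000208 (adjusted p = 0.132 with an estimated correlation). In p53 targets 6 were higher and 2 lower (11 and 2 adjusted over the list alone). The median was 0.36, with adjusted p = 0.00142 (adjusted p = 0.167 with an estimated correlation). DNA replication genes had 0 higher and 6 lower (0 and 8 adjusted over the list alone), with PCNA 2.14-fold lower. The median was -0.23, with adjusted p = 0.000385 (adjusted p = 0.355 with an estimated correlation). Heat shock genes had 1 and 6 (2 and 8 adjusted over the list alone). The median was -0.3, with adjusted p = 0.00277 (adjusted p = 0.355 with an estimated correlation). Homologous recombination and Fanconi repair genes had 1 and 5 of 16 (1 and 6 adjusted over the list alone), with BRCA1 1.97-fold lower (adjusted p = 0.000761). The median was -0.29, with adjusted p = 0.0382 (adjusted p = 0.327 with an estimated correlation). G-quadruplex helicases had 1 and 4 (2 and 5 adjusted over the list alone). The median was -0.36, with adjusted p = 0.0373 (adjusted p = 0.26 with an estimated correlation). Ribosome biogenesis genes had 0 and 4 of 20 (0 and 4 adjusted over the list alone). The median was -0.19, with adjusted p = 0.0382 (adjusted p = 0.571 with an estimated correlation). Ribosomal protein genes had 2 and 0 (0 and 0 adjusted over the list alone). The median was 0.11, with adjusted p = 0.015 (adjusted p = 0.571 with an estimated correlation). The adjusted p was 0.135 for recombination, 0.135 for helicases and 0.197 for ribosomal protein genes without replicate 1 of 5 µM, and 0.0726, 0.0722 and 0.135 without replicate 2 of 1 µM. For ribosome biogenesis it was 0.188 without replicate 1 of 1 µM, 0.45 without replicate 2 of 5 µM and 0.12 with fry, which gave 0.0818 for ribosomal protein genes.

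At 24 h the doses also differed in single genes. With 5 µM MT-CO3 was 6.64-fold lower than at 1 µM (log2 difference -2.73 ± 0.22, adjusted p = 1.53e-06) and TOP2A 2.22-fold lower (adjusted p = 0.000106). HSPA1L, a gene of the HSP70 family, was 13.3-fold higher at 7.42 ± 1.56 against 0.551 ± 0.277 CPM (log2 difference 3.74 ± 0.51, adjusted p = 0.000119), or 4.35 on that scale without replicate 1 of 1 µM. CDKN1A (0.3, adjusted p = 0.312), MYC (-0.02, adjusted p = 0.95) and TERT (0.19, adjusted p = 0.742) did not pass the test. Mitosis genes had 0 higher and 10 lower (0 and 14 adjusted over the list alone), with the mitotic kinase PLK1 1.43-fold lower. The median was -0.31, with adjusted p = 6.33e-06 (adjusted p = 0.0435 with an estimated correlation). Immediate-early genes had 5 and 0 (5 and 0 adjusted over the list alone), with EGR1 1.92-fold higher. The median was 0.55, with adjusted p = 0.00127 (adjusted p = 0.0496 with an estimated correlation). Mitochondrially encoded genes had 0 and 11 (0 and 12 adjusted over the list alone). The median was -1.59, with adjusted p = 2.54e-11 (adjusted p = 0.244 with an estimated correlation). Cholesterol biosynthesis had 0 and 7 (0 and 8 adjusted over the list alone). The median was -0.47, with adjusted p = 0.00175 (adjusted p = 0.651 with an estimated correlation). Endoplasmic reticulum chaperones had 0 and 7 (0 and 8 adjusted over the list alone). The median was -0.17, with adjusted p = 0.0154 (adjusted p = 0.6 with an estimated correlation). NF-kappaB targets had 5 and 0 (6 and 0 adjusted over the list alone). The median was 0.63, with adjusted p = 0.0252 (adjusted p = 0.631 with an estimated correlation). Calls for NF-kappaB targets were lost without replicate 1 of 1 µM (adjusted p = 0.181), without replicate 1 of 5 µM (0.134) and with fry (0.0645), and for cholesterol biosynthesis without replicate 2 of 5 µM (0.101) and with fry (0.0527). Of 2797 genes called, 985 were higher and 1812 lower, libraries did not overlap for 9626, and the count was 1250 without replicate 1 of 1 µM, 1015 without replicate 2 of 5 µM and 1381 in a fit to the compared libraries alone.

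The compounds were compared directly at the matched dose of 1 µM. At the early time point cAQ-mBen had NFKB1 6.81-fold lower than AQ-ac (log2 difference -2.77 ± 0.17, interval -3.12 to -2.42, adjusted p = 9.25e-08), MT-CYB 6.36-fold lower (-2.67 ± 0.17, -3.02 to -2.32, adjusted p = 9.25e-08) and C6orf52 14.8-fold higher (3.88 ± 0.34, 3.17 to 4.59, adjusted p = 2.58e-06). KRT18P55 had 238 counts with cAQ-mBen and 3 with AQ-ac (ratio 77.6, counting interval 26.2 to 379), with a log2 difference of 6.18, or 5.19 and 9.9 without replicate 1 or 2 of AQ-ac. GADD45A was higher with cAQ-mBen (0.67, interval 0.35 to 0.99, adjusted p = 0.0155), as was MYC, by 1.49-fold (0.58 ± 0.13, 0.31 to 0.85, adjusted p = 0.0127), a call lost without replicate 1 of cAQ-mBen (0.49, adjusted p = 0.115) and without replicate 2 of AQ-ac (0.45, adjusted p = 0.176). HSPA5 was lower (-0.40, interval -0.59 to -0.21, adjusted p = 0.0153). CDKN1A (-0.33, interval -0.73 to 0.08, adjusted p = 0.415), TERT (0.33, -0.30 to 0.96, adjusted p = 0.632), ICAM1 (0.03, -0.35 to 0.40, adjusted p = 0.963) and HMGCS1 (0.37, -0.16 to 0.91, adjusted p = 0.499) did not pass the test. For 92.6% of the 9253 genes with a mean of at least 10 CPM the interval of the difference lay within 2-fold. Of 744 genes called, 337 were higher and 407 lower with cAQ-mBen, libraries did not overlap for 8362, and the count was 403 and 299 without replicate 1 or 2 of cAQ-mBen and 298 and 273 without replicate 1 or 2 of AQ-ac.

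Mitochondrially encoded genes had 0 higher and 9 lower with cAQ-mBen (0 and 11 adjusted over the list alone). The median was -1.89, with adjusted p = 1.51e-12 (adjusted p = 0.232 with an estimated correlation). In the integrated stress response 3 were higher and 0 lower (4 and 0 adjusted over the list alone). The median was 0.32, with adjusted p = 0.00186 (adjusted p = 0.232 with an estimated correlation). DNA replication genes had 0 and 1 (0 and 2 adjusted over the list alone). The median was -0.19, with adjusted p = 0.0193 (adjusted p = 0.86 with an estimated correlation). G-quadruplex helicases also had 0 and 1 (0 and 2 adjusted over the list alone), with DHX36 1.78-fold lower (adjusted p = 0.000813). The median was -0.16, with adjusted p = 0.0193 (adjusted p = 0.232 with an estimated correlation). The helicase call was lost without replicate 1 of cAQ-mBen (adjusted p = 0.0772) and without replicate 1 of AQ-ac (0.133), and the replication call without replicate 1 of AQ-ac (0.21), without replicate 2 of cAQ-mBen (0.224) and with fry (0.258).

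At 24 h the compounds differed in genes such as MT-ND4 and CDKN1A. MT-ND4 was 12.7-fold lower with cAQ-mBen (log2 difference -3.67 ± 0.22, interval -4.14 to -3.20, adjusted p = 2.78e-08), WDR61 11.1-fold lower (-3.47 ± 0.19, -3.88 to -3.06, adjusted p = 8.45e-09) and C6orf52 29.3-fold higher (4.87 ± 0.35, 4.14 to 5.6, adjusted p = 1.12e-07). CDKN1A was 2.15-fold higher (1.1 ± 0.2, 0.69 to 1.52, adjusted p = 0.0017), TRIB3 2.13-fold higher at 112 ± 10.1 against 52.7 ± 0.364 CPM (1.09 ± 0.12, 0.84 to 1.34, adjusted p = 1.74e-05) and ICAM1 higher (0.79, 0.39 to 1.19, adjusted p = 0.0128). MYC (-0.03, interval -0.30 to 0.24, adjusted p = 0.919), TERT (0.26, -0.39 to 0.92, adjusted p = 0.656) and HMGCS1 (0.30, -0.23 to 0.83, adjusted p = 0.509) did not pass the test. CYP1A1 had 29 counts against 1 (ratio 30.9, counting interval 5.12 to 1260, adjusted p = 0.0731), which passed with no filter (0.00126), with the replicate block (0.0429) and without replicate 1 of cAQ-mBen (0.0487). The interval lay within 2-fold for 88.6% of the 9253 genes. Of 1873 genes called, 882 were higher and 991 lower, libraries did not overlap for 9251, and the count was 682 and 989 without replicate 1 or 2 of AQ-ac, 519 without replicate 2 of cAQ-mBen and 1190 in a fit to the compared libraries alone.

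Mitochondrially encoded genes had 0 higher and 11 lower with cAQ-mBen at 24 h (0 and 11 adjusted over the list alone). The median was -2.63, with adjusted p = 1.99e-14 (adjusted p = 0.143 with an estimated correlation). Integrated stress response genes had 7 and 0 (10 and 0 adjusted over the list alone). The median was 0.61, with adjusted p = 3.7e-05 (adjusted p = 0.117 with an estimated correlation). Apoptosis regulators had 3 and 0 (6 and 0 adjusted over the list alone). The median was 0.29, with adjusted p = 0.00915 (adjusted p = 0.117 with an estimated correlation). Cholesterol biosynthesis had 3 and 0 (5 and 0 adjusted over the list alone). The median was 0.3, with adjusted p = 0.0111 (adjusted p = 0.631 with an estimated correlation). The cholesterol call was lost without replicate 2 of cAQ-mBen (adjusted p = 0.0586) and with fry (0.196).

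In untreated cells, several inflammatory genes were far lower at 24 h than at the early time point. CXCL1 went from 34 ± 8.52 to 1.2 ± 0.553 CPM (28.8-fold lower, adjusted p = 0.000182), CXCL8 was 20.3-fold lower (adjusted p = 0.000206), TNFAIP3 17.7-fold lower (adjusted p = 4.23e-05), the NF-kappaB subunit gene RELB 6.51-fold lower (adjusted p = 4.23e-05) and ICAM1 3.61-fold lower (adjusted p = 5.45e-05). SERPINB2, an inhibitor of plasminogen activators, went from 502 ± 32 to 25.8 ± 14.2 CPM (log2 change -4.29 ± 0.42, adjusted p = 4.23e-05), or -4.99 without replicate 2 of the 24 h cells. ELF3, an epithelial transcription factor, rose 13.3-fold (log2 change 3.73 ± 0.57, adjusted p = 0.00201), with 2.68 and 4.32 without replicate 1 or 2 of the 24 h cells. CDKN1A was 2.41-fold lower (adjusted p = 0.0026), while MYC (-0.3, adjusted p = 0.213) and TERT (-0.69, adjusted p = 0.222) did not pass the test, although MYC did with no filter (adjusted p = 0.0391) and with the replicate block (0.0348). Of 529 genes called, 170 were higher and 359 lower, libraries did not overlap for 8370, and the count was 127 and 149 without replicate 1 or 2 of the early cells, 52 without replicate 1 of the 24 h cells, 1092 with no filter, 891 with DESeq2, 1019 with the replicate block and 289 in a fit to the compared libraries alone.

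NF-kappaB targets had 0 higher and 14 of 16 lower over time in untreated cells (0 and 15 adjusted over the list alone). The median was -2.48, with adjusted p = 5.73e-19 (adjusted p = 0.0213 with an estimated correlation). Immediate-early genes had 0 and 8 (1 and 8 adjusted over the list alone), with KLF6 2.56-fold lower. The median was -0.6, with adjusted p = 9.93e-05 (adjusted p = 0.0213 with an estimated correlation). Endoplasmic reticulum chaperones had 0 and 3 (0 and 7 adjusted over the list alone), with HSPA5 1.54-fold lower. The median was -0.23, with adjusted p = 0.000187 (adjusted p = 0.245 with an estimated correlation). Ribosome biogenesis genes had 0 and 4 (0 and 12 adjusted over the list alone). The median was -0.27, with adjusted p = 6.67e-06 (adjusted p = 0.386 with an estimated correlation). Epithelial-mesenchymal transition genes had 1 and 4 of 18 (1 and 5 adjusted over the list alone). The median was -0.24, with adjusted p = 0.0184 (adjusted p = 0.245 with an estimated correlation, but 0.0655 without replicate 2 of the early cells). With 1 member or fewer past the gene test, cholesterol biosynthesis was higher (median 0.21, adjusted p = 0.0381, and adjusted p = 0.634 with an estimated correlation), and ribosomal protein (median -0.07, adjusted p = 0.0199, and adjusted p = 0.634 with an estimated correlation) and mitochondrially encoded genes lower (median -0.3, adjusted p = 0.0184, and adjusted p = 0.634 with an estimated correlation). These 3 calls were lost with fry (adjusted p of 0.384, 0.14 and 0.302) and without single libraries. Cholesterol biosynthesis had 0.388 without replicate 1 of the early cells and 0.519 without replicate 2 of the 24 h cells, ribosomal protein genes had 0.394 and 0.0704 without replicate 1 of the early or 24 h cells, and mitochondrial genes had 0.374 without replicate 2 of the early cells and 0.479 without replicate 1 of the 24 h cells. Reads not aligned made up 4.26% ± 0.19 of the total in early libraries and 2.9% ± 0.23 at 24 h.

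The effect of 5 µM cAQ-mBen differed between times for many genes, tested as the difference of the log2 change at 24 h from that at the early time point. The heat shock gene HSPA1A had a difference of 2.94 ± 0.25 (adjusted p = 1.41e-06), with a 24 h change of -0.08 (adjusted p = 0.754), and the co-chaperone DNAJA1 had a difference of 1.33 ± 0.14 (adjusted p = 9.87e-06), with changes of -0.71 early and 0.62 at 24 h. MYC had a difference of -1.49 ± 0.18 (adjusted p = 4.11e-05) and TERT 2.16 ± 0.44 (adjusted p = 0.00316), while CDKN1A had 0.4 (adjusted p = 0.367). DDIT4, a stress-induced inhibitor of mTORC1 that shares 41.2% of its exonic bases with DDIT4-AS1, went from a rise of 1.72 to a fall with -1.66 (difference -3.39 ± 0.43, adjusted p = 6.79e-05). CDK18 had a difference of -4.58 ± 0.62 (adjusted p = 0.000123), CHAC1, a glutathione-degrading enzyme, -3.33 ± 0.54 (adjusted p = 0.00051), MT-ND4 -3.61 ± 0.3 (adjusted p = 1.35e-06) and MT-CO3 -3.49 ± 0.29 (adjusted p = 1.35e-06). The test called 2708 genes, 1144 with a positive and 1564 with a negative difference.

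Among lists, mitochondrially encoded genes had 13 of 13 with a negative difference (median -2.12, adjusted p = 4.5e-12, and adjusted p = 0.213 with an estimated correlation). Ribosomal protein genes had 0 positive and 19 negative (0 and 24 adjusted over the list alone), with RPL3 at -0.92 ± 0.12. The median was -0.41, with adjusted p = 1.03e-08 (adjusted p = 0.339 with an estimated correlation). Mitosis genes had 0 and 10 (0 and 15 adjusted over the list alone). The median was -0.41, with adjusted p = 3.21e-05 (adjusted p = 0.0714 with an estimated correlation). Integrated stress response genes had 0 and 8 (0 and 11 adjusted over the list alone). The median was -0.72, with adjusted p = 0.000198 (adjusted p = 0.205 with an estimated correlation). Heat shock genes had 7 and 2 (8 and 2 adjusted over the list alone). The median was 0.4, with adjusted p = 0.0136 (adjusted p = 0.466 with an estimated correlation). The heat shock call was lost without replicate 1 of the early untreated cells (adjusted p = 0.0563) and without replicate 1 of 5 µM cAQ-mBen at 24 h (0.0688).

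For 1 µM cAQ-mBen fewer differences between times passed. LUC7L3, a splicing factor gene, had a difference of 1.45 ± 0.2 (adjusted p = 0.00534) and WDR61 -2.48. MT-ND4 had -1.76 ± 0.29 (adjusted p = 0.0103), and 0.0806 without replicate 1 of the early untreated cells, 0.0671 without replicate 2 of the early and 0.0598 without replicate 2 of the 24 h cAQ-mBen cells. CDKN1A had 1.39 ± 0.28 (adjusted p = 0.0443), with 0.0642 and 0.187 without replicate 1 or 2 of the early untreated cells, 0.0865 and 0.106 without those of the 24 h untreated cells, 0.125 and 0.113 without those of the early cAQ-mBen cells, and 0.0569 and 0.101 without those of the 24 h cAQ-mBen cells. It was 0.0681 in a fit to the compared libraries alone and 0.0539 after thinning. Mitochondrially encoded genes had 0 positive and 2 negative differences (0 and 6 adjusted over the list alone). The median was -0.6, with adjusted p = 7e-05 (adjusted p = 0.685 with an estimated correlation, and 0.217 with fry). Ribosomal protein genes had 0 and 0 (0 and 2 adjusted over the list alone). The median was -0.2, with adjusted p = 5.94e-05 (adjusted p = 0.685 with an estimated correlation, and 0.109 with fry). The test called 66 genes, 26 positive and 40 negative. The count was 9 and 14 without replicate 1 or 2 of the early untreated cells, 18 and 41 without those at 24 h, 26 and 13 without those of early cAQ-mBen and 153 and 5 without those of cAQ-mBen at 24 h, and it was 460 with no filter, 292 with DESeq2, 265 with the replicate block and 18 in a fit to the compared libraries alone, of which 4 positive and 14 negative. For AQ-ac 0 genes passed the edgeR test, 580 had an unadjusted p under 0.05, DESeq2 called 0 and no filter gave 3. Endoplasmic reticulum chaperones were the 1 list past the test there (0 and 0 genes, 1 and 0 adjusted over the list alone). The median was 0.25, with adjusted p = 0.000117 (adjusted p = 0.675 with an estimated correlation, and 0.253 with fry).

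Effects of the 2 cAQ-mBen doses were compared across genes, which are not independent replicates and share untreated libraries. Log2 changes correlated at 0.629 at the early time point, where simulated unchanged groups against the same untreated libraries gave 0.5 (0.478 to 0.52), with a covariance of 0.2656 against 0.0744 simulated. Of 673 genes called at 1 µM, 79.6% were called in the same direction at 5 µM, with 228 higher in both where independent lists would give 29.7, 308 lower in both against 46.9, and 0 in opposite directions. At 24 h the correlation was 0.739 against 0.499 simulated and the covariance 0.4205 against 0.0743, with 760 genes higher in both against 157, 845 lower in both against 184 and 6 opposite, or 86.6% of the 1853 genes at 1 µM. Simulated groups held no change, so their shared calls (at most 4 early and 1 at 24 h) give no chance value. AQ-ac changes correlated with those of 5 and 1 µM cAQ-mBen at 0.324 and 0.355 at the early time point and at 0.246 and 0.325 at 24 h, below the simulated 0.499, 0.504, 0.5 and 0.496. Covariances exceeded the simulated median by 0.0286, 0.0122, 0.0141 and 0.005, the last (0.0791) within the simulated 0.0687 to 0.08. Part of any excess may come from the shared untreated libraries, as these 2 were not split.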

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

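The distance test below was chosen only after its result was seen, and the guanine, depth and GC tests after the data but before their results. The effect of 5 µM cAQ-mBen differed between the times for 2708 genes and that of 1 µM for 66, by the test of that difference.

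Negative differences for 5 µM were found for MYC (-1.49), the stress genes ATF3 (-2.88), GADD45A (-0.85), DDIT3 (-1.02), DDIT4 (-3.39), CHAC1 (-3.33) and SLC7A11 (-1.46), the inflammatory genes ICAM1 (-0.84), NFKBIA (-0.8) and NFKB1 (-1.13), and EGR1 (-1.94), KLF6 (-0.77) and ELF3 (-2.38). They were also found for the mitochondrial genes MT-CO3 (-3.49), MT-ND4 (-3.61), MT-CYB (-1.08), MT-ND5 (-2.13), MT-ND3 (-2.13) and MT-ND1 (-0.93). Further ones were CDK18 (-4.58), STK39 (-2.48), WDR61 (-2.89), AURKB (-0.39), TOP2A (-0.78), PLK1 (-0.63), CALR (-0.73), PDIA4 (-0.64), RPL3 (-0.92), RPLP0 (-0.51), RPS6 (-0.52) and FDPS (-0.75). Positive differences were found for TERT (2.16), the chaperone genes HSPA8 (2.7), HSPA1A (2.94), HSPA1B (2.97), HSPA1L (2.72) and DNAJA1 (1.33), and for ATG16L1 (2.75), BDKRB2 (2.84), NPIPB2 (2.73), BMP4 (3.42), SERPINB2 (2.54), RELB (1.25), ERCC3 (0.81), ZFYVE27 (0.95), MANF (0.5), IDI1 (0.86) and BRCA1 (0.76). Lists whose effect differed had median differences of -0.41 for mitosis, -0.72 for the integrated stress response, -0.41 for ribosomal proteins, -2.12 for mitochondrially encoded genes and 0.4 for heat shock (adjusted p = 0.0714 to 0.466 with an estimated correlation). For 1 µM the differences were 1.39 for CDKN1A, -1.76 for MT-ND4, -2.48 for WDR61, 1.45 for LUC7L3, -3.46 for HSPA1L, and, as list medians, -0.2 for ribosomal proteins and -0.6 for mitochondrially encoded genes (adjusted p = 0.685 with an estimated correlation for both). For AQ-ac endoplasmic reticulum chaperones had a median difference of 0.25 (adjusted p = 0.675 with an estimated correlation).

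Outside the gene counts, the share of reads not aligned lay in both libraries above both untreated libraries of that time for 1 µM cAQ-mBen at the early time point (mean 4.7%) and for 5 µM at the early time point (5.34%) and at 24 h (5.09%). Reads at more than 1 position lay below both untreated libraries in both libraries of every treated group but 1 µM cAQ-mBen at the early time point, furthest for 5 µM at 24 h (5.37% against 6.46%).

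Mitochondrial mRNAs fell by unequal amounts after 5 µM cAQ-mBen at 24 h. A candidate is early ending of the heavy-strand transcript. Log2 change and gene start (distance) had a Spearman rho of -0.79 over 12 mRNAs (permutation p = 0.0032). AQ-ac (same untreated libraries) had -0.502 (permutation p = 0.098). Early ending alone would not give smaller falls past MT-CO3 (-5.8), to -3.94 at MT-CYB, the last. A link to guanine content, predicted to be negative, had a rho of 0.148 (permutation p = 0.63), within its spread, and stays open. Unequal decay, a lower yield of mitochondrial RNA as part of the fall and cells of another state were not tested.

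Far more genes, 6267, were called for 5 µM cAQ-mBen at 24 h than for AQ-ac at 1 µM, with 0, where 568 genes had an unadjusted p under 0.05 in edgeR and DESeq2 called 0. Depth was argued against by thinning every library to the lowest gene total, which left 6149 calls, and 0 for AQ-ac. Removing a GC trend of up to 0.53 log2 per library left 6339, and 0 for AQ-ac. At the matched dose of 1 µM, 744 genes differed between the compounds at the early time point and 1873 at 24 h, so dose alone does not account for it. Why the compounds differ was not tested.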

How the results depend on the processing

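The thinning, GC and no-mitochondrial settings, and leaving out a library for the list tests and the correlations, were chosen only after the data were seen. No called change of a named gene reversed, and other genes were not checked for this. The balance of higher and lower calls turned over in 2 comparisons, for 5 µM cAQ-mBen at the early time point (47.7% higher) to 51.6% with the stricter filter, 50.8% with the GC trend removed and up to 51.1% without a treated library, and for 1 µM at 24 h (48.6%) to 50.6% with RLE, 50.3% with DESeq2 and 50.8% with the GC correction. RLE scaling, the stricter filter, thinning, the GC correction and leaving out mitochondrial genes left all 14 counts of genes within 1.5 times, and scaling moved the median change of all genes by at most 0.017 log2. Among values of named genes, DESeq2 kept the call for 352, gained 6 and lost 1, and leaving out a library kept 1510, gained 8 and lost 162, with fewer libraries in each fit. A lone library left in a group is assumed to vary like the other groups.

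With no filter on low counts AQ-ac had 14 genes at the early time point, 6 at 24 h and 3 for the difference between times, untreated cells over time 1092 (43.2% higher, against 32.1%) and the difference between times for 1 µM cAQ-mBen 460. DESeq2 gave 1 for AQ-ac at the early time point, 891 over time in untreated cells and 292 for the difference at 1 µM. A fit to the compared libraries alone gave 689 for 1 µM cAQ-mBen at 24 h, 1381 for 5 against 1 µM at 24 h, 1190 for cAQ-mBen against AQ-ac at 24 h, 289 over time in untreated cells and 18 for the difference at 1 µM. The cause was not tested.

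With the replicate block AQ-ac at the early time point had 2 genes, untreated cells over time 1019 and the difference at 1 µM 265, and the other 11 counts stayed within 1.5 times. Libraries of a replicate number deviated together with correlations of 0.057 to 0.268 over 28 group pairs, all positive and largest between 24 h groups. The main fit omits this shared replicate effect.

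Leaving out 1 library gave, in genes called, 1874 to 2804 for 5 µM cAQ-mBen, 236 to 348 for 1 µM and 0 to 0 for AQ-ac at the early time point, and 4235 to 5568, 485 to 1921 and 0 to 0 at 24 h. It gave 415 to 1111 and 1015 to 2938 for 5 against 1 µM at the early time point and 24 h, 273 to 403 and 519 to 1911 for cAQ-mBen against AQ-ac, 52 to 666 over time in untreated cells, and 1813 to 2524, 5 to 153 and 0 to 0 for differences between times with 5 µM, 1 µM and AQ-ac. Lists past the test numbered 9 to 10, 2 to 5, 1 to 2, 5 to 7, 2 to 6 and 0 to 2 for the treatments in the same order, 7 to 10 and 5 to 8 for dose, 2 to 4 and 3 to 6 for compound, 6 to 8 over time, and 4 to 5, 2 to 5 and 1 to 2 for differences between times. Of 69 list calls 43 were kept without any 1 library and 26 were lost at least once, and no filter, RLE and the block lost 0. Correlations, whose value for unchanged groups was not simulated with 1 library left out, ran from 0.548 to 0.701, 0.258 to 0.48 and 0.276 to 0.546 at the early time point (5 with 1 µM, 5 µM with AQ-ac, 1 µM with AQ-ac) and from 0.61 to 0.777, 0.157 to 0.399 and 0.215 to 0.515 at 24 h. Over genes called in either they were 0.774, 0.463, 0.46, 0.852, 0.342 and 0.438 in that order, and over genes of at least 5 CPM 0.668, 0.266, 0.274, 0.799, 0.2 and 0.207.

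With an estimated correlation 63 of the 69 list calls were lost, leaving 1 list for 5 µM cAQ-mBen at the early time point, 1 and 2 for dose at the early time point and 24 h, 2 over time and 0 elsewhere. Fry, which compares a set with no other genes, gave 15 for 5 µM at the early time point, 14 at 24 h, 10 for dose at 24 h, 8 and 1 for differences at 5 and 1 µM, and 0 for AQ-ac in each of 3 tests, and lost 17 calls. No filter gave 5 lists for 1 µM at the early time point, 11 for 5 µM at 24 h, 10 for dose at 24 h and 7 for the difference at 1 µM. At 11828558 to 17378653 counts per library the simulated recovery of 48% at 2-fold limits what a count of 0 excludes.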

Other observations

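The gene type, gene family and downstream-neighbour tests, and those of neighbours for all risers, were chosen only after results were seen, while the tests of an upstream neighbour and of an opposite-strand gene were chosen before. Long intergenic noncoding RNAs rose more often than they fell. With 5 µM cAQ-mBen at 24 h, 143 of 796 measured were higher and 48 lower, so 74.9% of called ones rose, against 46.2% of called protein-coding genes (2450 and 2851 of 12715, Fisher's exact test, adjusted p = 6.32e-14 over 18 tests). Early numbers were 78 and 32 with 5 µM (adjusted p = 1.58e-06) and 22 and 3 with 1 µM (1.1e-06). With 1 µM at 24 h, 40 and 17 gave 0.00228. Antisense genes, whose counts cannot be told from their partners', had 27 and 13 with 1 µM early (adjusted p = 3e-04). With 5 µM at 24 h they had 226 and 286 (0.619). Processed pseudogenes passed only with 5 µM early (19 and 5, 0.00438). Expression was not matched, and genes are not independent.

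Of 22 families taken by the start of their symbols, in 132 camera tests with a preset correlation and no estimated one, zinc finger genes named ZNF had 98 of 410 higher and 24 lower with 5 µM at 24 h (median log2 change 0.36, adjusted p = 0.0325). Solute carriers named SLC had 13 of 255 higher and 52 lower with 5 µM early (median -0.2, adjusted p = 0.0416). At 24 h they had 53 and 62 (median 0.01, adjusted p = 0.941). Genes named LINC had 13 of 220 higher and 0 lower with 1 µM early (median 0.19, adjusted p = 0.0378). With AQ-ac at 24 h, mitochondrial ribosomal protein genes (median -0.05, adjusted p = 0.0378) and proteasome genes (median -0.08, adjusted p = 0.0455) stood lower, with 0 members past the edgeR gene test.

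Among 443 genes that rose over 4-fold after 5 µM cAQ-mBen at 24 h, 26% had an expressed gene ending within 10 kb upstream on the same strand, above the upper end of 21.9% of the central 95% of 10000 lists matched on mean expression (median 18.5%), so transcription that runs on from an upstream gene may add to some of them. It does not cover all, since 74% (69.7 to 78.1, exact 95% interval) lacked such a neighbour, and of 125 upstream neighbours 23 were higher and 41 lower. A gene starting within 10 kb downstream was found for 18.1% (upper end 18.3), while for 1 µM at 24 h both sides lay above their limits (26.6% against 25.7, and 24.8% against 22) and for 5 µM at the early time point the upstream share did not (19.2% against 23.4) and for 1 µM it did (29.7% against 28.1). Among genes that fell over 4-fold the upstream share was 16.2% for 5 µM at 24 h (upper end 23.1). For 1 µM early it was 56.2% of 16 genes (37.5), 6 of them adjoining mitochondrial genes. Reads from exons of a tested gene on the opposite strand cannot be the source for all, as 69.3% (64.8 to 73.6) lacked such an overlap. The share with one, 30.7%, was below the matched median of 32.3% (upper end 36.6), though within its spread. That leaves this source open for some of the genes. Activation of the genes themselves was not tested.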
